A study of Mus musculus with 5 samples.

How the data were processed

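RNA was measured in dorsal pancreatic buds of mouse embryos at embryonic day 10.5, the stage at which the bud is a small epithelial outgrowth of the gut tube. Ptf1a is a basic helix-loop-helix transcription factor needed for pancreas development. Embryos came from matings of heterozygous parents, per the labels' protocols, so that null and heterozygous buds could be compared. The mesenchyme around each bud was dissected away mechanically before freezing, and each array was given RNA from a pool of 3 buds after 2 rounds of linear amplification primed from the poly(A) tail. There were 3 null arrays and 2 heterozygote arrays, all Affymetrix GeneChip Mouse Genome arrays of the same design. The labels describe separate pools but do not say which litters they came from, so p-values measure the spread between these pools.

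The deposited table holds a linear signal intensity for each of 45101 probe sets on each array. GCOS and RMA are named in the submitters' processing notes, with no version and no statement of which step each did. The plan made before the data were examined took the values for RMA output, which is on a log2 scale with equal distributions across arrays. The deposited intensities were linear instead, and the array medians spanned 0.354 on the log2 scale, so the plan's provision for that case was followed. Values were put on a log2 scale without an offset and quantile normalised across the 5 arrays. How background was subtracted before deposit is not given in the sources used here, and many intensities were close to 0, which makes the log2 values of dim probe sets scatter widely.

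The 64 control probe sets were left out of testing, leaving 45037. Gene names came from the platform annotation supplied with the data and were matched by gene ID to current mouse symbols, which succeeded for 34741 probe sets and changed 0 names. Of the tested probe sets, 34945 had 1 gene symbol, 932 had several and were not named, and 9160 had none in that table. Together they covered 18193 genes. No genomic positions are given, because no genome build for the arrays is given in the sources used here. The RefSeq gene table was used only for names and for the order of genes around Ptf1a.

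No detection calls were used. A background level was set on each array as the 95th percentile of 27 control probe sets for Bacillus subtilis genes, and it lay between 3.03 and 3.29 on the normalised log2 scale. The labels do not say whether these transcripts were added to the samples. Where a gene lay at or below this level on every array of a group, the fold is given as "at least", from the brighter group's mean against the higher of the background level and the measured value on each array of the dimmer group.

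Null and heterozygote arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with genotype as the sole term, two-sided tests and Benjamini-Hochberg adjustment over all 45037 probe sets at a threshold of 0.05. With 2 against 3 arrays the smallest p of an exact permutation test is 0.1, so no permutation test of a gene is given. A fit listed beforehand as the alternative lets the prior variance follow signal level and resists outlying variances (trended and robust eBayes). It is called the trended fit here, and the fit planned as primary is called the untrended fit. The decision to describe the trended fit at length was made after the untrended fit had called 0 probe sets.

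The fits were tested on simulated data for this comparison, with 200 of the 45037 probe sets changed. The 200 were drawn from probe sets at or above the median signal. When each probe set kept the spread estimated for it by the trended fit, the untrended fit recovered 0% of changes of 1, 2 or 3 on the log2 scale, and the trended fit recovered 13.4%, 56.7% and 77.3% with 5 calls among unchanged probe sets. Because the spreads were drawn from the trended fit's own estimates, that simulation favours the trended fit. When every probe set had the same SD of 0.809, both fits recovered 0%, 11.9% and 57.6%, with 2 calls among unchanged probe sets.

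A set of 28 gene lists was fixed before the data were examined, covering pancreatic cell fates, signalling pathways, stress and growth genes, and markers of other cell types that a dissected bud could hold. Each gene was represented by its probe set with the highest mean. Where a member's p is adjusted over its list alone, no adjustment was made for the 28 lists. Some such calls can therefore arise by chance. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with a correlation estimated from the residuals, and fry, were run beside it. The estimated form of camera rests on few residual degrees of freedom, so it can lose a call without correlation between members. The list test was also tested on simulated data: 4.6% of 1000 unchanged lists of 25 probe sets had an unadjusted p under 0.05, against 98% of 50 lists shifted by 0.5. The shifted lists were drawn from probe sets at or above the median signal. All probe sets were simulated independently, so the error rate for lists whose members vary together was not tested. The estimated correlation was 0.121 for mesenchyme, 0.274 for erythroid and 0.526 for endothelium markers.

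Genes were named by a rule fixed before the data were examined. It takes Ptf1a. It takes up to 15 falls and 15 rises with the largest change among called genes whose groups do not overlap. From each list it takes up to 4 called members, or the 2 with the lowest p where none was called. It also takes Pdx1, Mnx1, Nkx6-1, Onecut1, Sox9, Neurog3, Gcg, Cpa1, Shh and Cdx2 whatever their values, and 1 more gene that is not reported here. The rule was applied to both fits. Genes outside it are Itih5, Nr5a2, Onecut2, Hbb-bh1, Hbb-y, Bnip3, P4ha1, Xist and Eif2s3y, which were chosen after their values were seen.

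Alternatives listed before the data were examined were the trended fit, removal of probe sets below the median signal, median centring in place of quantile normalisation, array weights, the replicate number as a block, another threshold, a 2-fold minimum, 1 probe set per gene, an ordinary statistic without moderation, and leaving out each array in turn. For the lists they also included the mean of a gene's probe sets. An offset of 16 before the log2 step, no normalisation between arrays, and pool sex as a block were added after the data had been seen. Pool sex was coded by whether Xist lay above background at its brightest probe set. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.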

Results

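Expression was profiled in Ptf1a null (n = 3) and Ptf1a heterozygote (n = 2) dorsal pancreatic buds from E10.5 mouse embryos. Median signal was 17.5 and 14.4 on heterozygote replicates 1 and 2, and 16.4, 13.7 and 16.3 on null replicates 1 to 3. Between 60.9% and 65.2% of probe sets lay above the background level on each array. Signal from the 3' end of Gapdh exceeded that from its 5' end by 1.39 to 1.69 on the log2 scale, and for beta-actin the excess was 0.551 to 0.813. Correlations across probe sets ranged from 0.838 to 0.862 between arrays. Pairs of the same genotype correlated at 0.849 to 0.854, within the range of 0.838 to 0.862 between pairs of different genotypes. The number of arrays limits the precision of every value below.

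The comparison asks which transcripts differ in the early pancreatic bud when Ptf1a is lost. Ptf1a itself (probe set 1419424_at) had log2 signals of 7.10 and 7.33 in the heterozygotes and 5.21, 6.07 and 5.00 in the nulls. The mean was 7.22 ± 0.16 (SD, n = 2) in heterozygotes and 5.43 ± 0.57 (SD, n = 3) in nulls, a 3.46-fold lower signal (log2 change -1.79, SE 0.47). The difference did not pass adjustment (limma adjusted p = 0.651 in the untrended fit and 0.457 in the trended fit), although every null array lay below both heterozygote arrays. The labels do not say which part of the gene is deleted, so it is open whether this probe set can check the genotypes, and its signal in nulls was above background.

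Cpa1, which encodes the digestive enzyme carboxypeptidase A1 and marks early pancreatic progenitors, fell in the nulls. Its log2 signal was 6.12 ± 0.12 (SD, n = 2) in heterozygotes and below background on all 3 null arrays, at 0.89 ± 0.15 (SD, n = 3), so the signal was at least 8.08-fold lower. Mnx1, a homeodomain factor needed to form the dorsal bud, fell from 7.31 ± 0.01 (SD, n = 2) to 4.63 ± 0.42 (SD, n = 3), 6.40-fold. Both calls come from the untrended fit adjusted over the list alone, at limma adjusted p = 0.000595 for Cpa1 among 24 acinar and exocrine genes and 0.0328 for Mnx1 among 25 progenitor transcription factors. No adjustment was made for the 28 lists. Over all probe sets neither passed, with adjusted p = 0.363 and 0.369 in the untrended fit and 0.137 and 0.0612 in the trended fit. With an array left out, Cpa1 kept its call over the list alone each time (highest adjusted p = 0.0106, without heterozygote replicate 1). Mnx1 lost it each time, with log2 changes of -2.55 to -2.92 against -2.68 on all arrays, at 0.223 and 0.187 without heterozygote replicates 1 and 2 and at 0.0549, 0.151 and 0.0792 without null replicates 1, 2 and 3, and also with pool sex as a block (log2 change -2.61, adjusted p = 0.0916) and without normalisation (0.061).

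Across all 45037 probe sets the untrended limma fit called 0 at an adjusted p under 0.05, with a lowest adjusted p of 0.363. An unadjusted p under 0.05 was found for 2484 probe sets, against 2251.8 expected by chance. The ordinary statistic without moderation also called 0, and the trended fit called 8, with 2219 probe sets at an unadjusted p under 0.05.

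In the trended fit 3 genes fell. Chst2, a sulfotransferase that modifies carbohydrate chains, fell 11.3-fold (log2 change -3.50, trended SE 0.353, limma adjusted p = 0.00558), from 10.07 ± 0.07 (SD, n = 2) to 6.58 ± 0.75 (SD, n = 3). At its probe set 1460070_at both heterozygotes were above background and all 3 nulls below it. Parm1, which encodes a mucin-like membrane protein, fell 6.39-fold (log2 change -2.67, adjusted p = 0.0397), and Dap, a death-associated protein, fell 3.60-fold (log2 change -1.85, adjusted p = 0.00894).

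Slc2a3, Foxa1 and Nrp2 rose in the same fit. Both called probe sets of Slc2a3, the neuronal-type glucose transporter GLUT3, rose, by log2 changes of 1.68 and 2.03 (limma adjusted p = 0.00894 for each). Foxa1, a forkhead factor of the endoderm, rose 3.54-fold from 7.17 ± 0.06 (SD, n = 2) to 8.99 ± 0.25 (SD, n = 3), with adjusted p = 0.0219. Nrp2, a receptor for semaphorins and VEGF, rose 3.60-fold (log2 change 1.85, adjusted p = 0.0382), and its other 3 probe sets had log2 changes of 1.25, 1.80 and 3.72. A probe set without a gene name in the annotation used, 1438989_s_at, rose 2.93-fold (adjusted p = 0.0107). Itih5 missed the threshold at a log2 change of 2.09 and adjusted p = 0.0588. Names ending in _s_at or _x_at mark probe sets that can match several transcripts, which applies to Slc2a3, Dap and the unnamed probe set.

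Each of the 8 changes kept its sign in every alternative run. With an array left out this was bound to happen, since the groups did not overlap at any of the 8. The calls depend on each array. Without heterozygote replicate 1 the trended fit called 11 probe sets, of which 4 were among the 8, and Foxa1 (adjusted p = 0.0863), Parm1 (0.0973), Dap (0.0814) and 1 probe set of Slc2a3 (0.0671) lost their calls. Without heterozygote replicate 2 it called 4, of which 2 were among the 8, both of Slc2a3. It called 0 without null replicate 1, and 1 of the 8 without null replicate 2 or null replicate 3. Scaling changed the balance of the calls, from 5 rises and 3 falls to 1 rise and 3 falls with median centring and 0 rises and 2 falls without normalisation.

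**Figure D1:**
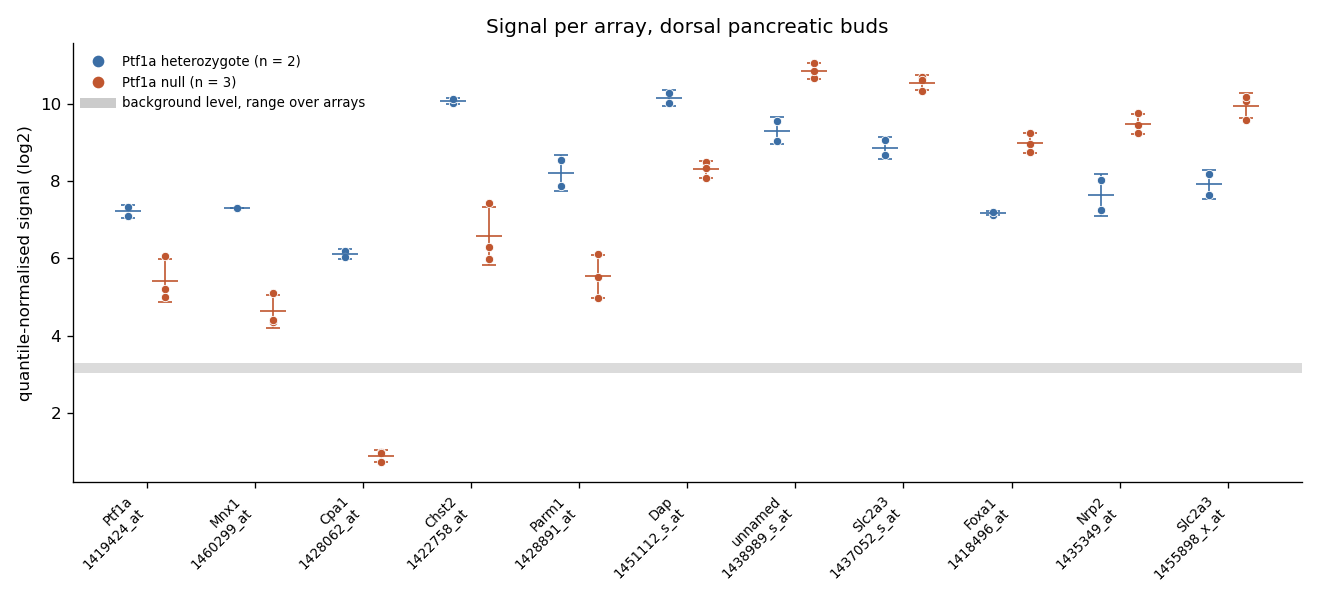
Quantile-normalised log2 signal (vertical axis) of Ptf1a, Mnx1, Cpa1 and the 8 probe sets called by the trended fit (horizontal axis), with a point per array, a dash for each group mean and bars of 1 SD. Cpa1 is the gene shown whose null arrays lie below the grey band, which spans the background levels of 3.03 to 3.29.

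Among 25 measured progenitor transcription factors, 10 were higher and 15 lower in nulls, and the list did not move as a whole (median log2 change -0.13, camera adjusted p = 0.487). Adjusted over the list alone, the untrended fit called 1 member, Mnx1, and the trended fit called 4. Those were Mnx1 and Nr5a2, a nuclear receptor, which fell (log2 changes -2.68 and -1.24), and Foxa1 and Onecut2, which rose (1.82 and 1.29). Fry's mixed test, which asks whether members change in either direction, gave an adjusted p of 0.000395. The mixed test also passed for acinar and exocrine genes (adjusted p = 0.000313) and for hypoxia and glycolysis genes (0.00576). Counts of called lists given for fry are of its directional test. Pdx1, the homeodomain factor that marks the pancreatic field, had log2 changes of -0.51 and -0.84 at its probe sets without passing any test (untrended adjusted p = 0.991 for the brighter). Nkx6-1 had -0.97, Onecut1 -0.37 and Sox9 -0.070, with adjusted p of 0.976 or more in the trended fit.

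Acinar and exocrine genes fell as a list, with 17 of 24 members lower and a median log2 change of -0.54 (camera adjusted p = 0.0357). The call was lost with an estimated correlation (adjusted p = 0.643 with an estimated correlation), although the estimate of 0.00159 lay below the preset 0.01. Apart from Cpa1, the named members did not pass on their own, among them Clps, a cofactor of pancreatic lipase, at -0.86 and adjusted p = 0.949. Relative to each member's mean over the arrays, the list's median was 0.48 and 0.62 on heterozygote replicates 1 and 2. On null replicates 1 to 3 it was -0.25, 0.27 and -0.42. It was highest on heterozygote replicate 2 and lowest on null replicate 3, where mesenchyme markers were lowest (-0.50) and highest (0.55). Only 4 members were above background on all 5 arrays, and all 4 were lower in nulls. With every value raised to at least the background level the median was -0.10, with median centring the list had adjusted p = 0.1, and its median ranged from -0.94 without heterozygote replicate 1 to -0.33 without null replicate 3. It also lost its call without heterozygote replicate 1 (0.0784), heterozygote replicate 2 (0.351), null replicate 1 (0.0709) or null replicate 3 (0.139), without dim probe sets (0.0817), without normalisation (0.126) and with an offset of 16 (median -0.097, adjusted p = 0.155).

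Islet hormone and granule genes had a median log2 change of 0.17 and camera adjusted p = 0.223. Gcg, which encodes glucagon, was bright in both groups, at 11.21 ± 0.91 (SD, n = 2) in heterozygotes and 11.54 ± 0.21 (SD, n = 3) in nulls (untrended adjusted p = 0.999). Iapp and Scg2 had log2 changes of 0.83 and 1.45, without passing. The list's median was 0.38 (adjusted p = 0.033) without heterozygote replicate 2 and -0.23 (adjusted p = 0.847) without heterozygote replicate 1. Endocrine transcription factors had a median of 0.077 and adjusted p = 0.831. Neurog3, the factor that starts endocrine differentiation, differed by -0.056 (adjusted p = 0.999). Sox4 rose by 1.20 at its brightest probe set in the trended fit adjusted over the list alone (adjusted p = 0.0181) and differed by 0.034 and -0.19 at 1419155_a_at and 1419156_at.

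Hypoxia and glycolysis genes rose as a list, with 19 of 24 members higher and a median log2 change of 0.26 (camera adjusted p = 0.019). The call was lost with an estimated correlation (adjusted p = 0.643 with an estimated correlation). Slc2a3 was its called member in the trended fit, over all probe sets and adjusted over the list alone (adjusted p = 1.29e-05 for the latter), and no member was called by the untrended fit. Bnip3 and P4ha1, chosen after their values were seen, had log2 changes of 0.87 and 1.26 without passing in either fit. Car9, a carbonic anhydrase induced by low oxygen, went the other way, with signal at background in all nulls and at least 3.25-fold lower than in heterozygotes (untrended adjusted p = 0.729). The list lost its call without either heterozygote, at adjusted p = 0.0988 without replicate 1 and 0.113 without replicate 2, at 0.178 without null replicate 1 and 0.0778 without null replicate 3, at 0.0961 with median centring, and at 0.126 without normalisation. Its median ranged from 0.13 without null replicate 3 to 0.34 without null replicate 2. Relative to each member's mean over the arrays, the list's median on null replicates 1 to 3 was 0.19, -0.073 and 0.20, lowest on the same array as that of mesenchyme markers (0.35, 0.025 and 0.55). On heterozygote replicates 1 and 2 it was -0.15 and -0.090, against 0.15 and -0.50 for mesenchyme.

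Mesenchyme markers rose as a list although mesenchyme had been dissected away: 25 of 29 members were higher in nulls, with a median log2 change of 0.45 (camera adjusted p = 0.00343; adjusted p = 0.643 with an estimated correlation). With every value raised to at least the background level the median was 0.25. Of the 16 members above background on all arrays, 15 were higher in nulls and 1 was lower. No member was called by either fit, over all probe sets or adjusted over the list alone. The members with the lowest p in the untrended fit were Osr1 (at least 1.20-fold higher) and Acta2 (log2 change 1.67, untrended adjusted p = 0.847). In the trended fit they were Nkx3-2 (at least 2.21-fold higher) and Acta2. Relative to each member's mean over the arrays, the list's median was -0.50 on heterozygote replicate 2 and 0.15 on heterozygote replicate 1. Without heterozygote replicate 2 the median was -0.0013 (adjusted p = 0.351), without heterozygote replicate 1 it was 0.70 (0.000422), and without null replicate 3 the call was lost (0.0778).

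Erythroid transcripts, which come from circulating primitive red cells at this stage, fell as a list. In nulls 16 of 19 members were lower, with a median log2 change of -0.82 (camera adjusted p = 0.000776; adjusted p = 0.643 with an estimated correlation). Adjusted over the list alone, 0 members passed in the untrended fit and 3 in the trended fit: the embryonic globins Hbb-bh1 (-0.81) and Hba-x (-1.31), and the red cell protein gene Ermap (-2.23), each at adjusted p = 0.0022. Probe sets of Hbb-y differed from each other, at -0.063 for the brightest and -0.88 for 1450621_a_at. Without heterozygote replicate 2 the list's median was -0.40 and its adjusted p 0.113, and without null replicate 3 they were -0.78 and 0.0778. Endothelium markers had a median of -0.12 (adjusted p = 0.944) and leukocyte markers -0.58 (adjusted p = 0.104). The leukocyte median was -0.95 (adjusted p = 0.0358) without heterozygote replicate 1 and -0.30 (adjusted p = 0.779) without heterozygote replicate 2, and -0.15 with values raised to background.

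Notch pathway genes had a median log2 change of -0.15 with 17 of 24 members lower (camera adjusted p = 0.113), and neural crest and glia markers one of 0.37 with 12 of 16 higher (adjusted p = 0.0681). Both lists passed in the trended fit, at adjusted p = 0.0439 and 0.0475, and neither did with an estimated correlation (adjusted p = 0.478 with an estimated correlation for each). The estimates in the untrended fit, 0.000574 and -0.0394, lay below the preset 0.01. The Notch median was 0.0078 without heterozygote replicate 1 and -0.38 without heterozygote replicate 2, with untrended adjusted p = 0.481 and 0.113. Notch1 and Hey1 differed by -0.999 and -1.05, without passing. The median of neural crest and glia markers was 0.225 with values raised to background and 0.19 with the offset of 16. Tfap2b, a neural crest transcription factor, rose by a log2 change of 2.50 in the trended fit adjusted over the list alone (adjusted p = 0.0118). Its other probe set, 1423340_at, was above background on 3 arrays and had a log2 change of 0.95 with overlapping groups.

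**Figure D2:**
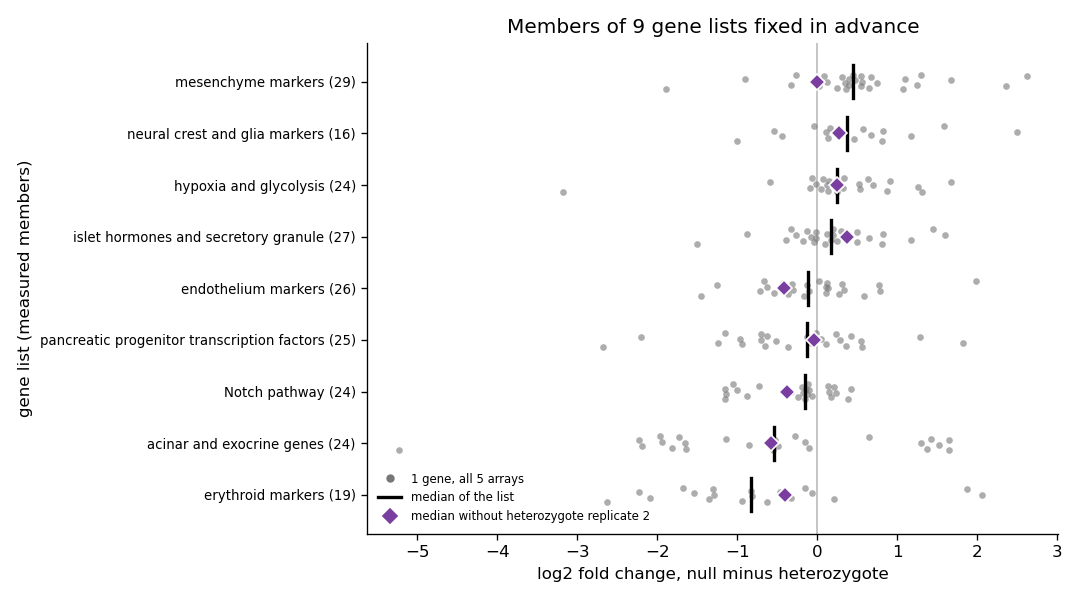
Log2 fold change, null minus heterozygote (horizontal axis), of each measured member of 9 gene lists (vertical axis), as grey points, with a black bar at each list's median over all 5 arrays and a diamond at its median without heterozygote replicate 2. The median of the mesenchyme list moves from 0.45 to -0.0013 and that of the erythroid list from -0.82 to -0.40.

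The other lists did not pass. Among signalling pathways the median log2 change was -0.095 for Hedgehog (camera adjusted p = 0.95) and 0.030 for Wnt (0.71). It was -0.089 for FGF receptor signalling (0.944) and -0.052 for BMP and TGF-beta (0.944). The Hedgehog ligand gene Shh had a log2 change of 1.64 at 1436869_at, with overlapping groups (untrended adjusted p = 0.991). That probe set was above background on 3 arrays. The other Shh probe set, 1427571_at, was above it on no array and had -0.94. Gut and liver genes had medians of 0.088 for intestine and stomach (0.95) and -0.078 for hepatobiliary genes (0.944), and Cdx2, an intestinal homeodomain factor, had a log2 change of 1.12 with overlapping groups. Only 6 of the 21 intestine and stomach members were above background on all arrays, and those 6 were higher in nulls. With values raised to background that list's median was -0.060, so dim members limit it. Medians were -0.029 for cell cycle genes (0.61), 0.049 for p53 targets and cell death (0.944), -0.17 for the unfolded protein response (0.424) and -0.31 for immediate early and heat shock genes (0.386). They were -0.045 for epithelial junctions and keratins (0.944), -0.069 for neuron markers (0.95), -0.18 for mesothelium (0.71) and -0.033 for notochord and floor plate (0.944). Sex-linked transcripts had -0.50 (0.944), ribosomal proteins -0.044 (0.944) and oxidative phosphorylation -0.041 (0.944). Median, mean and test differed in sign for Hedgehog, intestine and stomach, hepatobiliary, p53, neuron, mesothelium, notochord, sex-linked and ribosomal genes.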

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

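The offset of 16, the fit without normalisation, the pool sex block and all combinations of the trended fit with other settings were chosen after the data had been seen. The untrended fit called 0 probe sets in every setting and with each array left out, and the trended fit called 8. Combined with the trend, the count was 4 with median centring, 79 with the replicate block and 2 without normalisation, and it ranged from 0 to 11 with an array left out. All 8 probe sets kept their sign throughout, which was bound to happen with an array left out because their groups did not overlap. The number of called lists, 4 at first, was 2 with median centring, 0 with the replicate block, 2 without normalisation, 0 with an estimated correlation, 0 with fry, and 0 to 4 with an array left out. It was 6 with the trend, 5 without dim probe sets and 5 with the offset of 16, where the acinar list lost its call and the Notch and neural crest lists gained one, and 4 with array weights, the pool sex block or the mean of probe sets. The median log2 change of all probe sets was -0.117 without normalisation and -0.00991 with it. Replicate numbers are shared by 2 pairs of arrays whose deviations correlated at -0.0555 and 0.0496. With 2 heterozygotes the deviation of 1 mirrors that of the other, so these correlations cannot show whether a litter or day was shared. Xist at 1427262_at was low on both replicate 1 arrays (0.25 and 2.27). It was high on both replicate 2 arrays (10.58 and 11.61) and on null replicate 3. The replicate block also ended the call of Mnx1 over its list alone (log2 change -2.57, adjusted p = 0.201) and leaves 1 residual degree of freedom. Null replicate 3 is the sole array of its number, so the block gives it a term of its own. The block's log2 changes are therefore those found without null replicate 3, such as -3.92 for Chst2 in both. Its 79 calls rest on the other arrays, and the block is not a separate check of effect sizes. An array left out can leave 1 heterozygote, which is then assumed to vary like the nulls. The log2 change of Ptf1a stayed between -2.11 and -1.57 with an array left out. The cause of these shifts was not tested. Signal over background limits the acinar, leukocyte, mesothelium, and intestine and stomach lists, with 4, 3, 1 and 6 members above background on all arrays.

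Directions turned 51 times for lists and 14 times for named genes, always with no call in either setting. Median log2 changes where the direction of the list test turned were as follows. Without dim probe sets they were -0.095 for Hedgehog, -0.089 for FGF receptor signalling, 0.29 for intestine and stomach and -0.085 for immediate early genes. With the mean of probe sets they were 0.061 for endocrine factors, -0.16 for Hedgehog, 0.088 for intestine and stomach, -0.0034 for epithelial junctions, -0.033 for notochord and 0.089 for sex-linked transcripts. With the trend they were -0.089 for FGF receptor signalling, 0.088 for intestine and stomach and -0.045 for epithelial junctions, and with fry 0.088 for intestine and stomach. With the replicate block they were -0.070 for Hedgehog, -0.16 for p53 targets and -0.23 for sex-linked transcripts, and the changes of Sox9 and Neurog3 were 0.28 and 0.17. With the pool sex block they were 0.028 for p53 targets, 0.068 for neurons and -0.40 for sex-linked transcripts. For intestine and stomach they were 0.052 with median centring, 0.094 with the offset and 0.0077 without normalisation, which gave -0.67 for sex-linked transcripts.

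With an array left out, medians of lists whose direction turned ranged from -0.28 to 0.59 for endocrine factors, -0.23 to 0.38 for islet genes, -0.40 to 0.25 for Hedgehog, -0.17 to 0.058 for FGF receptor signalling, -0.098 to -0.0034 for BMP and TGF-beta, -0.093 to 0.12 for intestine and stomach, -0.16 to 0.29 for hepatobiliary genes, -0.16 to 0.11 for p53 targets and -0.38 to -0.011 for immediate early genes. They ranged from -0.38 to 0.065 for epithelial junctions, -0.42 to 0.22 for endothelium, -0.12 to 0.12 for neurons, -0.036 to 0.59 for mesothelium, -0.20 to 0.32 for notochord, -0.84 to -0.23 for sex-linked transcripts, -0.16 to 0.083 for ribosomal proteins and -0.17 to 0.075 for oxidative phosphorylation. Log2 changes ranged from -0.62 to 0.48 for Sox9, -0.95 to 0.84 for Neurog3, -0.31 to 0.97 for Gcg, -0.12 to 3.40 for Shh, -0.27 to 2.52 for Cdx2, -0.056 to 2.38 for Rps27, -0.88 to 0.090 for Cycs, -0.015 to 3.98 for Pecam1 and -0.0039 to 5.00 for Wt1.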

Other observations

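The tests on the mesenchyme and erythroid lists below were chosen after those lists had been seen, and some replaced earlier ones. The carry-over test replaced a count of members that could not tell either, and the tests against heterozygote replicate 1 replaced tests that left out replicate 2, which was bound to shrink both changes and had spoken for a low mesenchyme content of that array (median -0.0013 without it). The pool sex block was added after the data had been seen. Some genes outside the leading groups passed in the trended limma fit adjusted over the list alone, which makes no adjustment for the 28 lists. Afp, which encodes the fetal serum protein alpha-fetoprotein, rose by a log2 change of 1.54 (adjusted p = 0.00701 over the hepatobiliary list), which was 0.79 without heterozygote replicate 1 and 2.28 without heterozygote replicate 2. Krt18, a keratin of simple epithelia, rose by 0.67 (0.0319 over the epithelial list). Ihh, a Hedgehog ligand of the gut epithelium, was below background in both heterozygotes and at least 2.46-fold higher in nulls (0.039 over the Hedgehog list). None passed over all probe sets.

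Xist, the transcript that coats the inactive X chromosome, had log2 signals below background at its brightest probe set, 1427262_at, on heterozygote replicate 1 (0.25) and null replicate 1 (2.27). Its probe sets 1427263_at and 1436936_s_at were above background (3.08) on null replicate 1, at 3.35 and 3.65, and below it on heterozygote replicate 1, at 1.70 and 1.41. At 1427262_at it was 10.58, 11.61 and 11.25 on heterozygote replicate 2 and null replicates 2 and 3. The Y-linked gene Eif2s3y lay between 7.17 and 8.39 on all 5 arrays at 1417210_at.

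The trended fit called 8 probe sets for the genotype split, and 1 of the 10 splits of the 5 arrays into 2 and 3 gave as many. The highest count of another split was 2, for the split that follows Xist, and 10 splits are too few for a share under 0.05. A block for pool sex cannot decide on embryo sex. Each genotype held arrays with Xist above and below background at 1427262_at, so the block could hardly shrink changes picked for differing between genotypes. With the block the median absolute change of the 8 was 1.027 times that without, and 7 stayed called. The block also treats as alike pools whose Eif2s3y signal at 1417210_at was 8.22 (heterozygote replicate 2), 7.55 and 7.17 (null replicates 2 and 3). DNA of another strain carried around Ptf1a is not decided either. Of its 100 nearest measured genes 5 had an unadjusted p under 0.05, against 4.48% of other genes (one-sided Fisher's exact p = 0.467). A change in only a few neighbours would not show in that share. Among the 100 were 0 called genes, so the named called genes lie outside that stretch. Heterozygote replicate 1 and null replicate 1, both with Xist below background at 1427262_at, still differed at all 8. Chst2 was 10.02 and 6.31, Parm1 7.89 and 4.99, and Dap 10.30 and 8.50. Foxa1 was 7.13 and 9.26 and Nrp2 8.03 and 9.76. Slc2a3 was 8.67 and 10.70, and 7.65 and 10.08, and the unnamed probe set 9.55 and 10.66. On the arrays with Xist above background the groups did not overlap at the 8 either. These values argue against embryo sex, as marked by Xist, as the source of the 8. The loss of Ptf1a stays open as the cause, as do DNA of another strain and chance.

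Mesenchyme markers were higher in the nulls, and a low mesenchyme content of heterozygote replicate 2 stays open as the source. Against heterozygote replicate 1 alone, the list's median difference was 0.244, 0.035 and 0.501 on null replicates 1, 2 and 3, with standard errors over members of 0.156, 0.194 and 0.173. It passed 2 standard errors on null replicate 3 alone, so the remaining heterozygote does not decide. These standard errors, like those for erythroid and endothelium markers below, measure spread over members that can vary together, and not spread between pools. Carry-over of more mesenchyme in every null pool stays open as well, since the lowest of these differences was within its standard error of 0. An effect of genotype on mesenchyme was not tested apart from dissection and cannot be told apart from carry-over here.

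Erythroid transcripts were lower in the nulls, and a high blood content of heterozygote replicate 2 stays open as the source. Against heterozygote replicate 1 alone, the list's median difference was -0.192, -0.514 and -0.629 on null replicates 1, 2 and 3, with standard errors over members of 0.177, 0.330 and 0.237, and it passed 2 standard errors on null replicate 3 alone. Fewer blood vessels in nulls stays undecided too, since endothelium markers had a median of -0.116, with a standard error over members of 0.149, against a bound of -0.41. That median turned with a single array, to -0.416 without heterozygote replicate 2 and 0.216 without heterozygote replicate 1. A difference in blood content between genotypes stays open as a biological explanation and was not tested apart from these.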
